A study of Mus musculus with 6 samples.

How the data were processed

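RNA of mouse F9 teratocarcinoma cells was made into libraries with a TruSeq RNA kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The cells grew in medium with charcoal-stripped serum, which holds little retinoid of its own, and were left untreated or given 1 µM all-trans RA for 48 hours before harvest. The 6 libraries form 6 groups of 1 library each, from 3 lines (shGFP, shCtbp2, shRxr) at 2 treatments, and the labels name no replicate culture of a line. The groups were taken from the labels of each library.

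Reads were aligned with TopHat 1.4 to mm9 and counted per Ensembl gene with HTSeq, per the submitters' processing notes. The HTSeq version, the counting mode, the strand setting and the annotation release are not given in the sources used here. The deposited table holds log2 values, which the authors made from the reads of each gene scaled to 10000000 reads counted in genes per library, plus 1. This was read from the values: each library's unlogged values sum to 10000000, and dividing them by the value of 1 read gave whole numbers for 100% of values, within 1e-06 of a read. The whole reads so recovered give depths of 12416100 (shGFP_UT), 13322506 (shGFP_RA), 12089782 (shCtbp2_UT), 10103347 (shCtbp2_RA), 11947894 (shRxr_UT) and 9955808 (shRxr_RA). Counts were log2-transformed by the authors before deposit, so tests written for a table of counts were not the main tests. All columns of values matched a library by name, and 0 were left over. Of the gene symbols 25 had been turned into dates and were restored from the gene identifiers, and 918 symbols belong to several identifiers.

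Levels are unlogged values, called normalised reads (reads per 10000000 counted in genes). Folds are ratios of these levels, with 95% intervals from the exact binomial interval of the reads (Clopper-Pearson); intervals of single levels are exact Poisson intervals. All cover counting error only, not differences between cultures or libraries. Against a library with no read, a fold is given as at least N-fold, computed against a floor of 3 reads in that library (2.25 to 3.01 normalised reads). Log2 changes are on the scale log2(value + 10), which understates the change of low genes. Genes with a mean of at least 20 over the 6 libraries were tested, 12332 of 23886 with a read in a library. With 1 library per group no test within a group was possible, and genes were counted by size, at least 2-fold on that log2 scale. The difference in RA response is the log2 change of a knock-down line minus that of shGFP, counted at 1 or more.

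A test was possible where lines or treatments stood in as replicates. The limma trend model (limma 3.58.1, R 4.3.3) had line and treatment as terms over all libraries, with 2 residual degrees of freedom and 11.2 prior degrees of freedom. It gave the RA effect over the lines and the shCtbp2 and shRxr effects over both treatments, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Its residual holds the differences between lines in RA response. On simulated data with the real means, 98% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold by RA were recovered among 12332. Of the calls 6.16% were false. The simulated genes had the same RA response in every line, unlike the real ones, so these shares do not describe the fit to the real libraries. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

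Gene lists, 24 in all, were direct RA targets and retinoid metabolism, anterior Hox, posterior Hox, primitive endoderm regulators, parietal endoderm and basement membrane, visceral endoderm, pluripotency, neuroectoderm, mesoderm and primitive streak, trophoblast, nuclear receptor coregulators, CtBP complex members, epithelial junction and keratin, mesenchymal, fibroblast, blood and immune, cell cycle, p53 targets and cell cycle inhibitors, interferon response, unfolded protein and stress response, glycolysis and hypoxia, cholesterol synthesis, imprinted genes, and BMP, Wnt and FGF signalling. For each, the count of limma calls is given over all genes and adjusted over the list alone. The list's median log2 value is placed as a percentile among 10000 random lists of the same size matched on deciles of mean expression; below 2.5 or above 97.5 a list is said to stand apart. This describes the libraries and is no p-value. The lists overlap: 5 of the 20 RA targets, for example, stand in another list. Sox1, Pou3f1, Tpbpa, Lum, Hbb-b1, Tyrobp, Hmgcs1 and Peg1 had no value under these symbols.

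Genes were named by a rule: the targets and paralogs (Ctbp2, Ctbp1, Rxra, Rxrb, Rxrg); for RA the 10 highest and 10 lowest by mean log2 change among genes with a mean of at least 50, an adjusted p under 0.05 and the same direction in all lines; for each knock-down the 10 highest and 10 lowest by the smaller of the untreated and RA log2 differences, in the same direction; for each difference in RA response the 10 most positive and 10 most negative; and any list member. Symbols of predicted, small or unnamed genes were passed over, and a few genes that met the rule are not reported here. Groups, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined.

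Lines were compared by Pearson and Spearman correlation and the reduced major axis slope across genes. Overlaps are set beside those of independent lists of the same sizes, and correlations that share the shGFP libraries beside values simulated for unchanged lines. GC content and length are those of each gene's longest transcript in the GRCm38 annotation, matched by identifier for 98.4% of tested genes; coordinates are mm9, as deposited. The GC and length correction removed, in 20 bins, each library's trend in its deviation from the mean of all libraries. Alternatives were a pseudocount of 1 or 50, no filter, a mean of at least 100, equal totals, equal upper quartiles, limma without its trend, without the block on line and without each line in turn. Median-of-ratios scaling, the GC and length correction, limma voom on the recovered reads and a fit without the shCtbp2_RA library were added after seeing the data.

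Without a known strand setting, reads of a gene and of an overlapping or antisense partner, as in the Hox clusters, cannot be separated, and adjacent genes such as Dmgdh and Bhmt2, Hapln4 and Ncan, or Mylpf and Sept1 may share reads. Gapdh is uncertain because of its pseudogenes. The 34 genes without an entry in the annotation stayed in the counts. Nothing in the labels said which receptor the shRxr hairpin targets beyond its name.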

Results

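RNA sequencing was done on mouse F9 cells, a teratocarcinoma line that turns into endoderm-like cells when given retinoic acid (RA). Each of 3 lines carried a short hairpin RNA: shGFP, the control, shCtbp2, against the transcriptional corepressor Ctbp2, and shRxr, against the retinoid X receptor that pairs with RA receptors on DNA. Each line was sequenced untreated (UT) and after 48 hours in 1 µM all-trans RA, which gave 6 libraries and 1 library per group. Between 9955808 and 13322506 reads per library were counted in genes, the fewest in shRxr_RA and the most in shGFP_RA. Of the 25904 deposited genes, 12332 passed the minimum on expression. Within a group there was no replicate, so a difference between 2 libraries has no replicate check. Such differences are given as folds, with intervals for counting error only.

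Ctbp2 was lower in the shCtbp2 line, and of the retinoid X receptor genes Rxra was lower in the shRxr line, whose labels do not name the receptor gene. Ctbp2 (ENSMUSG00000030970, mm9 chromosome 7, 140179246 to 140316037) stood at 1811 normalised reads in shGFP_UT and 701 in shGFP_RA, against 210.1 in shCtbp2_UT and 55.4 in shCtbp2_RA. It was 8.62-fold lower in the shCtbp2 line untreated (95% counting interval 7.57 to 9.85) and 12.6-fold lower in RA (9.65 to 16.9), and in the shRxr line it stood at 1632 and 1132. Over all 3 lines Ctbp2 also fell with RA (log2 change -1.21, SE 0.29, adjusted p 0.014). Its paralog Ctbp1 (ENSMUSG00000037373, chromosome 5, 33590372 to 33617618) stood at 1127 in shCtbp2_UT and 2155 in shCtbp2_RA, against 1141 and 1699 in shGFP. Rxra (ENSMUSG00000015846, chromosome 2, 27531960 to 27618477) stood at 73.7 in shRxr_UT and 82.4 in shRxr_RA, against 520 and 805 in shGFP and 372 and 821 in shCtbp2. It was 7.06-fold lower untreated (5.65 to 8.93) and 9.78-fold lower in RA (7.81 to 12.4). Rxrb was at 638 and 546 in the shRxr line against 605 and 673 in shGFP. Rxrg, at 4.50 to 18.5 in the 6 libraries, was below the minimum for testing.

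**Figure D1:**
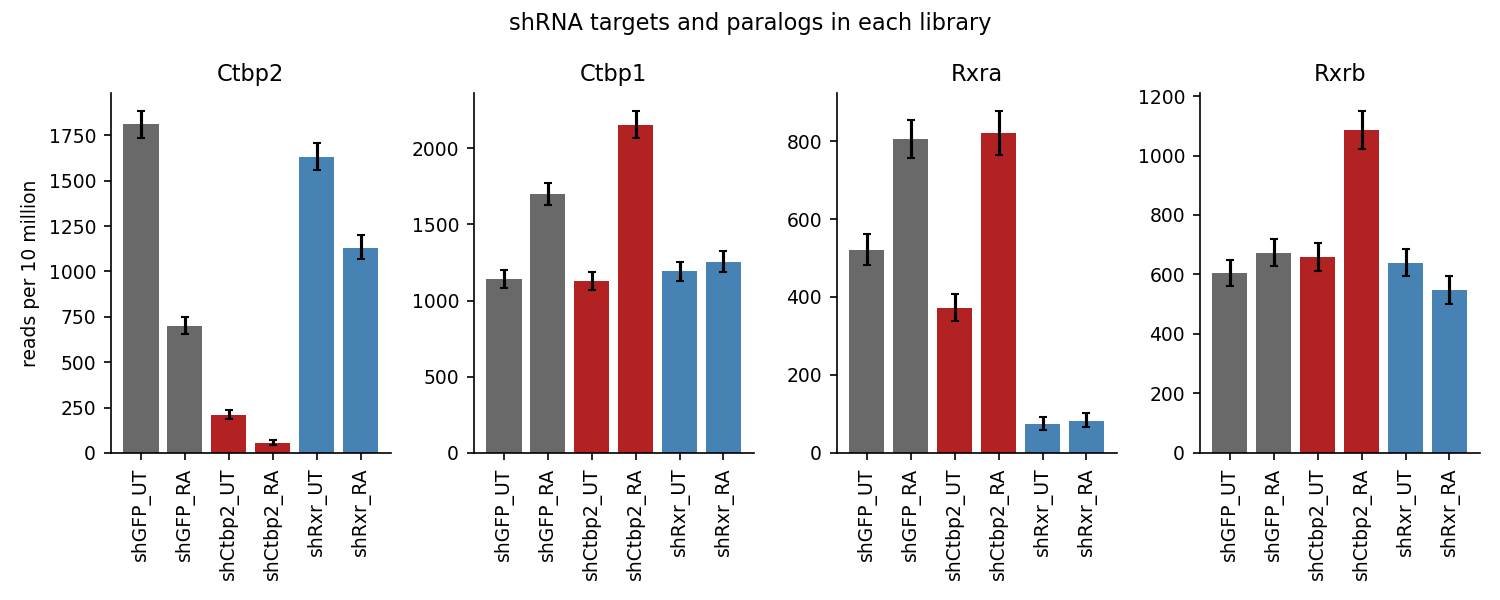
Bars give the level of each gene in normalised reads (reads per 10000000 counted in genes) in the 6 libraries (1 library per bar) and error bars the 95% counting interval. Ctbp2 is 8.62-fold lower in shCtbp2_UT than in shGFP_UT and Rxra 7.06-fold lower in shRxr_UT, while neither paralog, Ctbp1 or Rxrb, is 2-fold lower in any library.

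The first comparison asked which genes RA moved alike in all 3 lines. The genes that rose most included known direct targets of RA receptors. Stra8, a gene of the meiotic programme (ENSMUSG00000029848, chromosome 6, 34870163 to 34889342), rose by a log2 of 6.61 (SE 0.50, adjusted p 1e-05), and Cyp26a1, which breaks RA down (ENSMUSG00000024987, chromosome 19, 37772298 to 37776018), by 6.53 (SE 0.38, adjusted p 2.2e-06). In shGFP Stra8 went from 18.5 to 6428 normalised reads, a 347-fold difference (231 to 548), and Cyp26a1 from 8.86 to 2894, a 327-fold difference (182 to 655). Among those that followed, with log2 changes from 5.86 to 4.43, were Zfp703, Stra6 (the retinol uptake receptor), Cdx1, Hoxa5, Pmp22, Ptges and Gpr124. Otx2, an anterior neural and pluripotency regulator (ENSMUSG00000021848, chromosome 14, 49277354 to 49287319), fell by 3.82 on the log2 scale (SE 0.33, adjusted p 2.1e-05), the largest fall, followed by Pou4f2 (-3.50), Evx1 (-3.37), Coch (-3.20), Trh (-3.06), Enox1 (-3.0), Aire (-2.92) and Zmat4, Lgals3 and Grhl2 (each -2.86).

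Of 20 direct RA targets and retinoid metabolism genes 18 rose and none fell, and 20 rose when adjusted over the list alone. Among the members that did not pass over all genes was Bhlhe40 (log2 0.86, adjusted p 0.058). Anterior Hox genes, which pattern the head-to-trunk axis, rose in all 10 measured members of 15 and in all 10 when adjusted over the list alone. Hoxb5, with no read untreated, was at least 62.4-fold higher in shGFP. Hoxa5, with 3 reads in shGFP_UT, was 274-fold higher there, with an interval of 93.3 to 1330. The list's median log2 change was 4.39 in shGFP, 3.59 in shCtbp2 and 2.93 in shRxr, and 5.0, 3.87 and 3.40 with genes at 0 set to the floor of 3 reads. Of posterior Hox genes 5 of 16 were measured and 4 rose (4 adjusted over the list alone), with medians of 1.83, 1.81 and 1.57.

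**Figure D2:**
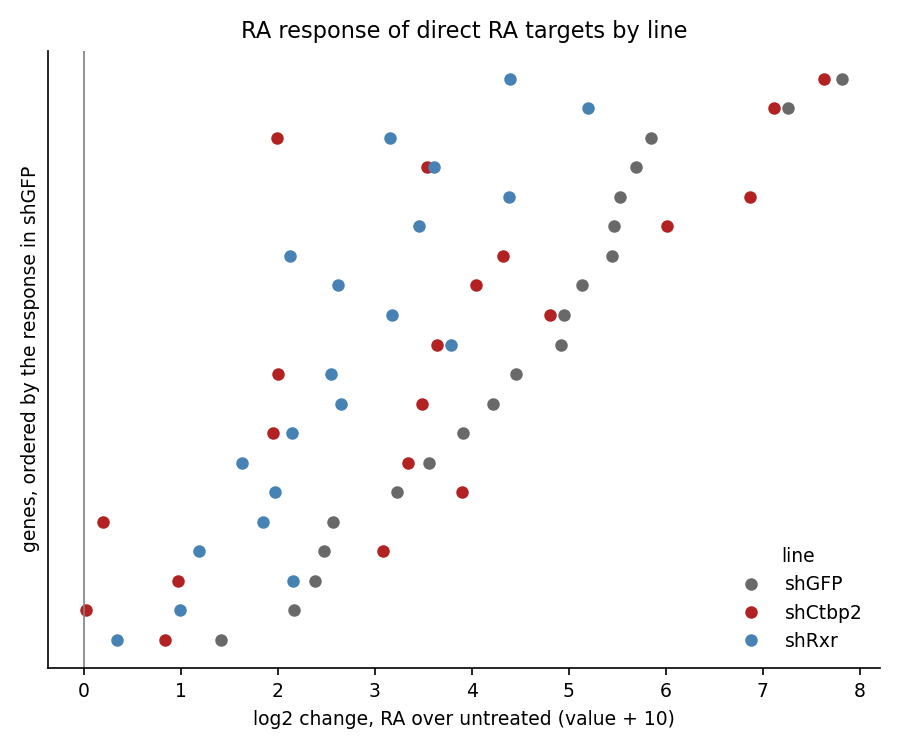
Each row is 1 of the 20 direct RA targets, ordered by the response in shGFP, and each point its log2 change, RA over untreated on the scale of value + 10, in the shGFP, shCtbp2 or shRxr line. The median change is 4.69 in shGFP, 3.51 in shCtbp2 and 2.59 in shRxr, and 18 of 20 genes lie at least 1 log2 unit lower in shRxr than in shGFP.

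Endoderm genes were in 3 lists. Among 11 regulators of primitive endoderm 9 rose and 1, Hnf4a, fell (10 and 1 adjusted over the list alone). Gata6 rose by a log2 of 4.07 (SE 0.29, adjusted p 7.7e-06), and in shGFP it was 24.8-fold higher (17.9 to 35.5), with Gata4 5.68-fold (4.88 to 6.65), Foxa2 48.6-fold (20.6 to 151) and Dab2 8.30-fold higher (6.91 to 10.04). The list's median was 2.83 in shGFP, 1.69 in shCtbp2 and 1.90 in shRxr. Of 18 measured genes of parietal endoderm and basement membrane 12 rose and 1, the activin antagonist Fst, fell (14 and 1 adjusted over the list alone), with medians of 1.73, 1.19 and 0.88. The collagen genes Col4a1 and Col4a2 were 4.63-fold and 5.60-fold higher in shGFP, Lama1 4.18-fold, the collagen chaperone Serpinh1 6.26-fold (5.93 to 6.62) and Plat 23.6-fold. Of 17 visceral endoderm genes only 5 were measured, of which Cubn and Ihh rose (3 up and 1 down adjusted over the list alone), with medians of 1.82, 0.34 and 0.93.

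Pluripotency genes fell in part. Of 28 members 12 fell and none rose (14 fell adjusted over the list alone). Tdgf1 fell by 2.12 (SE 0.35, adjusted p 0.0015), Zfp42 by 1.52 (SE 0.32, adjusted p 0.0060) and Sox2 by 1.23 (SE 0.29, adjusted p 0.012) on the log2 scale. Pou5f1, with a log2 change of -0.36 (adjusted p 0.47), and Nanog, with -0.53 (adjusted p 0.20), did not pass the test. In shGFP Pou5f1 was 2.13-fold lower (2.08 to 2.18) and Nanog 2.07-fold lower, in shRxr Pou5f1 was 1.39-fold lower, and in shCtbp2 it was 1.41-fold higher (1.39 to 1.44). The list's median was -1.06 in shGFP, -0.71 in shCtbp2 and -0.47 in shRxr. After the correction for GC content and length it was -1.04, -0.79 and -0.43. The Pou5f1 and Nanog folds are not corrected, and values of the shCtbp2_RA library were higher at higher GC content.

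Of 8 measured neuroectoderm genes Pax6 and Sox3 rose and Otx2 fell (3 and 2 adjusted over the list alone). Of 4 mesoderm and primitive streak genes Wnt3 rose and Evx1 fell, and of 6 trophoblast genes Gata3 and Esx1 rose. Mesenchymal genes gave 1 rise, Snai1, and 1 fall, Thy1, among 9 (2 and 1 adjusted over the list alone). Markers of fibroblasts, 4 measured of 12 and 2 of the 12 held in another list, gave 3 rises (Col5a1, Pdgfrb, Fbln1) and the same fall of Thy1, with a median of 1.72 in shGFP (percentile 99.9), while none of 3 measured blood and immune genes passed. In the epithelial list Krt18 and Krt19 rose and Cdh3 and Esrp1 fell among 17.

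Of 16 measured genes of BMP, Wnt and FGF signalling Bmp7, Smad6, Wnt3a and Dusp6 rose, and Bmp4 (log2 -1.88), Id1, Id3, Fgf4, Spry2 and Spry4 (-1.92) fell. Imprinted genes gave 6 rises (H19, Igf2, Dlk1, Ndn, Plagl1, Sgce) and 1 fall (Snrpn) among 17. Igf2, a fetal growth factor, was 21.5-fold higher in shGFP (16.7 to 28.1). In the glycolysis and hypoxia list 5 of 19 fell and none rose (6 adjusted over the list alone), Ldha by 1.04 on the log2 scale (adjusted p 0.029) beside Pfkp, Bnip3, Pdk1 and Gapdh, which has many pseudogenes and is uncertain. In the cell cycle list Ccnd1 (-1.47), Myc (-1.25) and Mycn (-1.50) fell and the other 20 of 23 did not pass. Cdkn2a (1.14, adjusted p 0.023) was the only call among 16 p53 targets and cell cycle inhibitors. The interferon list gave 2 rises (Oasl2, Ifi35) and 1 fall (Ddx58) among 6, the stress list 2 rises (Atf3, Xbp1) among 14, and cholesterol synthesis 1 rise among 17. Among 19 nuclear receptors and coregulators Rarb, Nrip1 and Nr2f2 rose and Ctbp2 fell. Of 14 CtBP complex members 1 rose and 1, Ctbp2, fell (1 and 2 adjusted over the list alone). Where no other count is given, the count adjusted over the list alone was the same. After the correction for GC content and length the glycolysis list had 1 raised and 11 lowered, direct RA targets 20 and 0, pluripotency 0 and 15, epithelial genes 2 and 5 and neuroectoderm 2 and 3, and no other list moved by more than 1 in either direction. Of the calls in the lists 2 were lost, Snrpn, from a log2 of -0.94 (SE 0.26) to -0.36 (SE 0.21, adjusted p 0.23), and Pfkp, from -1.0 (SE 0.27) to -0.69 (SE 0.23, adjusted p 0.055), in both because the fall became smaller.

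Across all genes limma, with line as a block, called 1327 genes raised and 571 lowered by RA at an adjusted p of 0.05 (3819 at an unadjusted p of 0.05, where chance gives 617). Of the calls 69.9% were raised, against 57.9% when libraries were scaled to equal upper quartiles, which called 1330 and 966, and 55.9% with median-of-ratios scaling (1324 and 1043). Without the shGFP line the counts were 375 and 89, without shCtbp2 564 and 193, without shRxr 1747 and 1498, and without the shCtbp2_RA library alone 565 and 207, of which 513 and 179 were among the calls from all libraries.

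The lines were then taken one by one. After RA 1649 genes were at least 2-fold higher and 872 at least 2-fold lower in shGFP, 1864 and 2377 in shCtbp2, and 649 and 180 in shRxr. Of the 1649 genes higher in shGFP 1128 (68.4%) were also at least 2-fold higher in shCtbp2, where independent lists of these sizes would share 249.2, and 578 (35.1%) in shRxr, where they would share 86.8. Seen from shRxr, 578 of its 649 higher genes (89.1%) were higher in shGFP. Of the 2377 genes lower in shCtbp2 660 (27.8%) were lower in shGFP and 122 (5.13%) in shRxr. Across genes, which are not independent replicates, log2 responses of shGFP and shCtbp2 had a Pearson r of 0.77 (rho 0.73), those of shGFP and shRxr 0.79 (rho 0.67), and those of shCtbp2 and shRxr 0.51 (rho 0.35). The reduced major axis slope on shGFP was 1.19 for shCtbp2 and 0.58 for shRxr. Values of the shCtbp2_RA library were higher at higher GC content across genes (Spearman 0.65 for its deviation from the mean of all libraries). The same correlation was 0.25 in shGFP_RA and -0.44 to -0.40 in shRxr_RA and the untreated libraries. The RA response itself correlated with GC content at 0.37 in shGFP, 0.62 in shCtbp2 and -0.06 in shRxr. A correction for GC content and length therefore cannot tell a library bias from an RA response that follows GC content. After the correction the shCtbp2 slope was 0.99. Genes higher and lower with RA then numbered 1708 and 531 in shGFP, 1452 and 869 in shCtbp2, and 594 and 187 in shRxr.

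**Figure D3:**
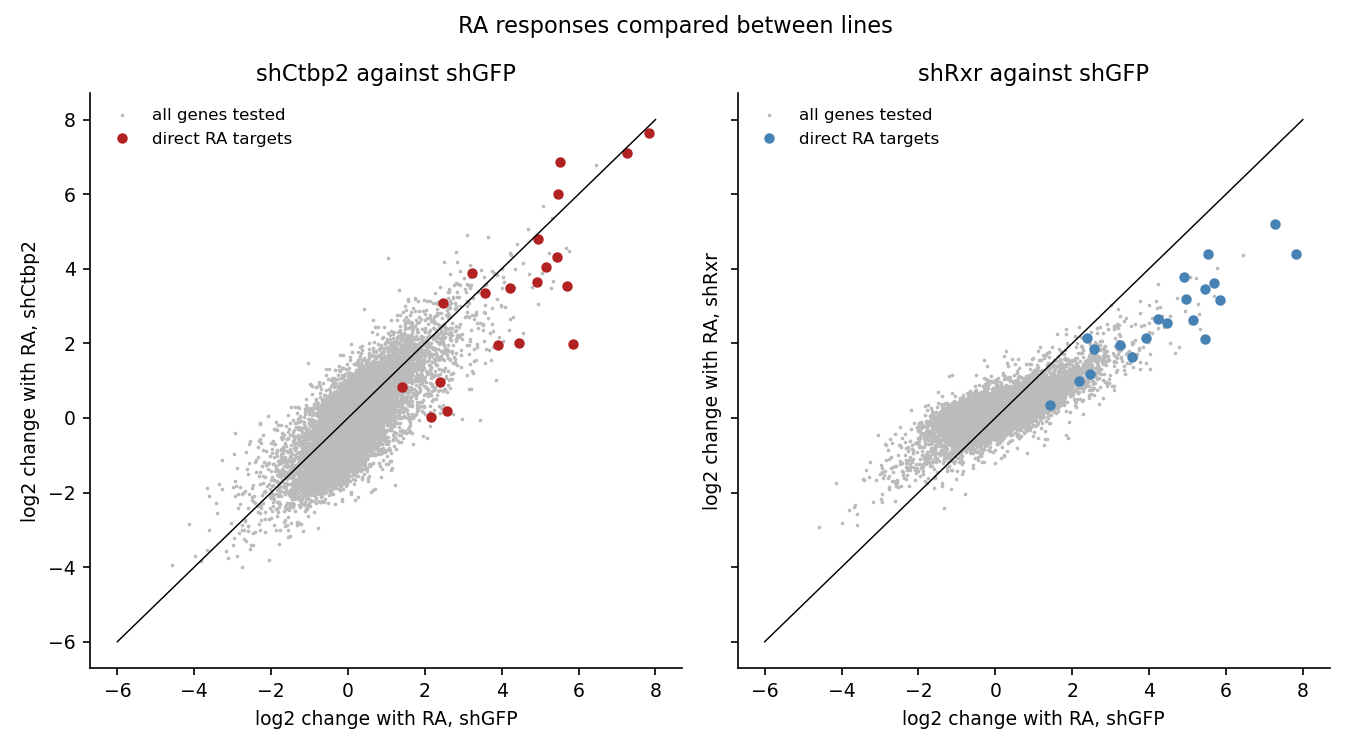
Points are genes; axes give the log2 change with RA in shGFP (x) and in shCtbp2 or shRxr (y), with the line of equal response in black and the 20 direct RA targets in colour. The shCtbp2 responses have a slope of 1.19 on shGFP over all genes and the shRxr responses 0.58, and all 20 direct targets lie below the line of equal response in the shRxr panel.

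The next comparison set the shCtbp2 line against shGFP at each treatment, to ask which genes depend on Ctbp2 with or without RA. Untreated, 172 genes were at least 2-fold higher and 288 lower in shCtbp2. Among genes higher at both treatments were Atp2a3, a calcium pump of the endoplasmic reticulum (ENSMUSG00000020788, chromosome 11, 72774671 to 72806546), 5.80-fold untreated (5.18 to 6.50) and 6.85-fold in RA (6.03 to 7.80), Lgals3, or galectin-3, 3.39-fold (3.09 to 3.72) and 12.3-fold (8.89 to 17.4), Krt17, 4.16-fold and 13.9-fold, and Ly6a, the Sca-1 antigen, 4.80-fold and 6.55-fold. Dmgdh (6.91-fold and 5.15-fold) and Bhmt2 (6.93-fold and 4.33-fold), enzymes of choline metabolism, are neighbours on chromosome 13, and Serpinb6c, Grin1, Myl7 and Gpx2 were also among the 10 highest. Krt8 was 5.84-fold higher untreated (5.23 to 6.54) and 2.61-fold higher in RA (2.44 to 2.80).

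Among genes lower at both treatments, Meg3 (ENSMUSG00000021268, chromosome 12, 110779211 to 110809936) was 5.86-fold lower untreated (4.73 to 7.33) and 8.60-fold lower in RA (6.24 to 12.1), and Rian (ENSMUSG00000091793, chromosome 12, 110842155 to 110899919) 5.50-fold (4.59 to 6.64) and 8.69-fold (6.96 to 11). Both are maternally expressed non-coding RNAs of the imprinted Dlk1-Dio3 cluster. Notch3 was 3.72-fold and 3.71-fold lower, and the neighbours Hapln4 (9.74-fold and 4.57-fold) and Ncan (log2 differences of -2.13 and -1.76), which encode parts of the brain matrix, were lower too. The imprinted list had a median log2 difference of -0.49 untreated (below all matched random lists, 5 of 17 at least 2-fold lower) and -1.46 in RA (likewise below all, 11 of 17). It was lower in the shRxr line as well, against the same shGFP libraries, with medians of -0.22 untreated and -0.51 in RA, both below all matched lists, and 0 and 1 of 17 at least 2-fold lower. In RA the paternally expressed Igf2 was 7.67-fold lower (6.46 to 9.15), Peg3 7.56-fold (6.73 to 8.50) and Peg10 5.09-fold (4.86 to 5.33). The BMP, Wnt and FGF list had an untreated median of -0.27, at percentile 0.01 of matched lists, and the epithelial list 0.21, at percentile 99.9. Pluripotency (0.07), stress (0.12) and cholesterol synthesis (0.15) also stood apart above the matched lists untreated, and coregulators (-0.18) and p53 targets (-0.23) below them.

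At both treatments 71 genes were at least 2-fold higher and 155 lower, where independent lists would share 5.47 and 42.8, and 7 went opposite ways. These counts were 104, 279 and 25 with a pseudocount of 1 and 26, 28 and 2 with 50. The limma contrast over both treatments raised 13 genes and lowered 5 (1091 at an unadjusted p of 0.05, where chance gives 617). Atp2a3 (log2 2.61, SE 0.33, adjusted p 0.0093), Krt17 (2.61), Lgals3 (2.5), Serpinb6c (2.41), Ly6a (2.39), Dmgdh (2.38), Grin1 (2.24), Myl7 (2.23), Gpx2 (2.13) and Bhmt2 (2.11) rose, and Ctbp2 (-3.25, SE 0.36, adjusted p 0.0060), Rian (-2.67, SE 0.33, adjusted p 0.0093) and Meg3 (-2.62, SE 0.34, adjusted p 0.010) fell. The other calls, Ckmt1, Cyp2s1 and Capn5 raised and Tro and Mtap7d2 lowered, lie outside the rule for named genes and were looked up after their values were seen. Among the imprinted genes 2 fell, and 8 when adjusted over the list alone (Igf2, Mirg, Peg3, Peg10, Igf2r and Plagl1 beside Meg3 and Rian). Besides Ctbp2, no gene of the other lists was called over all genes. Adjusted over the list alone, Pdgfra (log2 -1.24), Dab2 (-1.05) and Lrp2 (-1.71) of the primitive endoderm list fell, Krt8 (1.94) of the parietal endoderm and epithelial lists rose, and Lamb1 and Plat of the former fell. Adjusted in the same way, Amn and Lrp2 passed in the visceral endoderm list, Pax6 and Nes in neuroectoderm, Hoxd9 and Hoxc13 in posterior Hox, 1 gene beside Ctbp2 in CtBP complex members, Bst2 in interferon response, and Wnt3a and Id2 in BMP, Wnt and FGF signalling. With voom on the recovered reads, a pseudocount of 1 or a mean of at least 100 limma called 1 and 3, in each case Atp2a3, Ctbp2, Rian and Meg3. With no filter it called 0 and 0 (1762 at an unadjusted p of 0.05, where chance gives 1194). The split of 13 and 5, or 72.2% raised, was 43 and 35 (55.1%) with equal upper quartiles, 42 and 44 (48.8%) with median-of-ratios scaling and 12 and 12 (50%) after the correction for GC content and length. Without the shCtbp2_RA library limma, with 1 residual degree of freedom, called 0 genes (743 at an unadjusted p of 0.05), Ctbp2 having a log2 difference of -2.84 (SE 0.31, adjusted p 0.36). No line had a second library at the same treatment, so the contrast cannot separate the hairpin from other differences between the cultures.

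**Figure D4:**
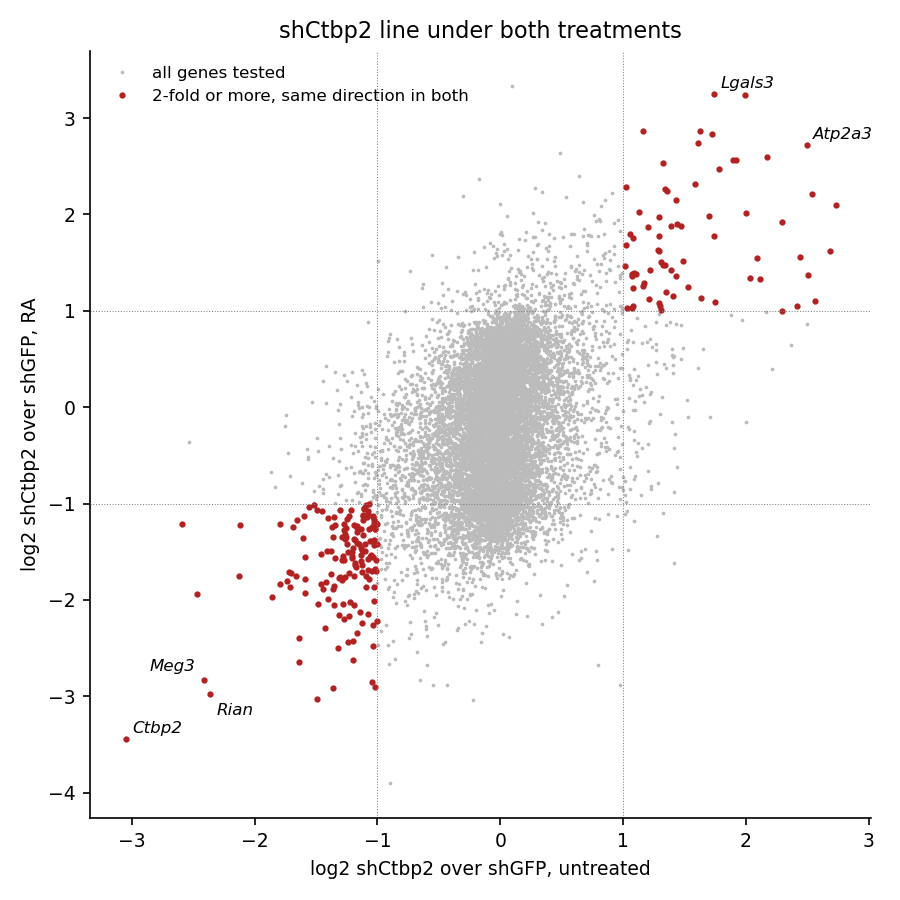
Points are genes; axes give the log2 difference of shCtbp2 from shGFP untreated (x) and in RA (y), with dotted lines at 2-fold. The 71 genes at least 2-fold higher and the 155 lower at both treatments are in red, with Ctbp2, Meg3 and Rian at the lower left and Atp2a3 and Lgals3 at the upper right.

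In RA the shCtbp2 line had 392 genes at least 2-fold higher and 1831 lower than shGFP. Of 28 pluripotency genes 9 were at least 2-fold higher and none lower, among them Pou5f1 3.07-fold (3.0 to 3.14), Esrrb 2.73-fold, Klf2 2.75-fold and Dppa5a 3.42-fold, and the list median was 0.34 at percentile 99.0 (members from -0.91 to 2.40). The glycolysis list had a median of 0.68, above all matched lists, with 4 of 19 members at least 2-fold higher and 1 lower, and Ldha was 2.19-fold and Aldoa 2.04-fold higher. Nuclear receptors and coregulators had a median of -1.06, below all matched lists, with 10 of 19 members at least 2-fold lower and 1 higher. Ep300 was 2.78-fold (2.59 to 2.98), Crebbp 2.71-fold and Ncor1 2.15-fold lower (2.04 to 2.26), while Rarg was 2.30-fold higher. These lists moved with the GC trend of the shCtbp2_RA library: in the lowest GC bin its median deviation was -0.77, in the highest 0.56. After the correction for GC content and length the list medians were 0.21, 0.25 and -0.37, at percentiles 99.5, 99.1 and 1.56, and the counts became 305 higher and 930 lower. With equal upper quartiles the split was 886 higher and 965 lower, and with median-of-ratios scaling 596 genes were higher. The median of all genes was -0.19 in the deposited scaling, 0.04 with equal upper quartiles and -0.06 with median-of-ratios scaling.

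**Figure D5:**
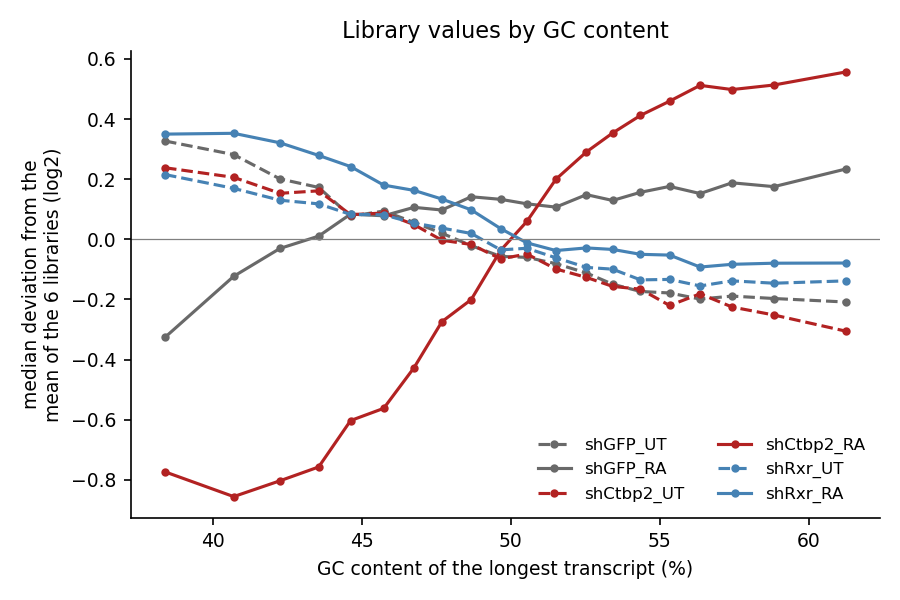
Lines give, for each library, the median log2 deviation from the mean of the 6 libraries (y) in 20 bins of genes by GC content of the longest transcript (x, %). The shCtbp2_RA library goes from -0.77 at a median GC content of 38.4% to 0.56 at 61.2%. Between the same bins shGFP_RA goes from -0.33 to 0.23 and shRxr_RA from 0.35 to -0.08.

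The design's main question was whether the knock-down altered the response to RA. For direct RA targets the log2 response was lower in shCtbp2 than in shGFP by a median difference of -0.92 (percentile 0.01 of matched lists), with 10 of 20 genes lower by at least 1 and 1 higher. Crabp2, an RA-binding protein (ENSMUSG00000004885, chromosome 3, 87752588 to 87757298), was 96.5-fold higher with RA in shGFP (60.9 to 163) and 4.76-fold in shCtbp2 (3.43 to 6.73), the most negative difference of the named genes (-3.85). Stra8 was 347-fold higher in both lines, with an interval of 213 to 607 in shCtbp2, and Cyp26a1, with 6 untreated reads, was 416-fold higher in shCtbp2 (191 to 1134). On the scale of log2(value + 10) their responses differed from those in shGFP by -0.19 and -0.15, and by -0.54 and -0.72 after the correction for GC content and length. Anterior Hox genes had a median difference of -1.01 (percentile 0.14). The random lists were not matched on size of response, so these percentiles do not set the lists apart from other genes with strong responses. The parietal endoderm list (-0.54, percentile 3.99) and the primitive endoderm list (-0.35, percentile 25.1) stood apart only after the correction for GC content and length (-0.60, percentile 0.02, and -0.64, percentile 0.73).

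Over all genes 335 responses were higher by at least 1 log2 unit in shCtbp2 and 1535 lower. Fry (-3.03), Fras1 (-3.0), Thsd4 (-2.82), Clgn (-2.62), Amot and Rragd (each -2.60), Il17rd (-2.59), Prdm1 (-2.56) and Gpr161 (-2.53) followed Crabp2. Tlx2 (3.24), Nphs1 (2.55), Mylpf (2.52), Sept1 (2.15), Pla2g10 (2.14), Foxd3 (2.0), Slc28a1 (1.93) and Hsd17b14, Inhbb and Ggt1 (each 1.90) had the most positive differences. After the GC and length correction the genes from Tlx2 to Ggt1 had 1.21 (Hsd17b14) to 2.52 (Tlx2), and those from Fry to Gpr161 -2.74 to -1.83. Mylpf and Sept1 are adjacent on chromosome 7 and may share reads. The pluripotency list had a median difference of 0.59 and glycolysis 0.61, both above all matched lists, and each was 0.24 after the correction for GC content and length. The imprinted list had -0.61 (percentile 2.10), or -0.68 (percentile 0.05) after the correction, and the cell cycle list 0.35 (percentile 98.9), which no longer stood apart after it (0.11, percentile 96.0). The counts were 218 higher and 734 lower after the GC and length correction, and 879 and 769 with equal upper quartiles.

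For the shRxr line, the comparison with shGFP asked which genes depend on the receptor. Untreated, 48 genes were at least 2-fold higher and 8 lower. Several RA targets were higher without added RA: Stra8 10.4-fold (6.76 to 16.7), Cdx1 4.68-fold (2.69 to 8.61), Foxa1 4.50-fold and Rarb 3.90-fold (1.24 to 16.1). Gpr124, an RA-induced gene outside that list, was 4.70-fold higher (3.52 to 6.38). The direct RA target list had an untreated median of 0.30, above all matched lists, with 3 of 20 at least 2-fold higher, and the anterior Hox list 0.27 (percentile 99.4). The endoderm lists went the other way where they stood apart, primitive endoderm at -0.19 (percentile 0.73) and visceral endoderm at -0.25 (percentile 1.47). Neuroectoderm (0.28), fibroblast (0.26), stress (0.18) and cholesterol synthesis (0.11) stood apart above the matched lists and glycolysis (-0.17) below them. The fibroblast list, with 4 measured genes, no longer stood apart after the correction for GC content and length (0.25, percentile 96.3). In RA the RA target and anterior Hox lists were lower than in shGFP, with medians of -1.28 and -1.29, both below all matched lists, and 11 of 20 RA targets at least 2-fold lower. Cyp26b1, a second RA-degrading enzyme, was 15.4-fold lower (11.5 to 21.1), Cyp26a1 5.68-fold (5.18 to 6.25) and Stra8 1.51-fold lower.

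In RA 461 genes were at least 2-fold higher and 323 lower in shRxr. The pluripotency list had a median of 0.69, above all matched lists, with 8 of 28 members at least 2-fold higher and none lower (members from -0.67 to 1.80), and Tdgf1 was 3.59-fold, Zfp42 2.82-fold and Sox2 2.10-fold higher. The epithelial list had a median of -0.26 untreated and -0.76 in RA, below all matched lists at both treatments, with 0 and 7 of 17 members at least 2-fold lower, and in RA Krt18 was 5.81-fold (4.61 to 7.39) and Krt8 2.77-fold lower. After the correction for GC content and length 162 genes were higher and 343 lower in RA. Values of this comparison were lower at higher GC content across genes (Spearman -0.52). The deviation of shRxr_RA from the mean of all libraries correlated with GC content at -0.42, near the untreated libraries (-0.44 to -0.40). That of shGFP_RA correlated at 0.25, so of the 2 libraries it was the control that departed from the untreated ones.

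Few genes differed alike at both treatments in shRxr: 5 were higher and 1, Rxra, was lower, where independent lists would share 1.79 and 0.21, and 4 went opposite ways (9, 23 and 27 with a pseudocount of 1). Inhbb, a subunit of activin B (ENSMUSG00000037035, chromosome 1, 121312042 to 121318825), was 2.30-fold higher untreated (2.11 to 2.5) and 3.17-fold higher in RA (2.94 to 3.44). Nhs, Cpt1a and Myo1f were 2.25-fold, 2.19-fold and 4.72-fold higher untreated, and Pitpnm3 was 2.10-fold lower untreated and 10.5-fold lower in RA, which is outside the count because its untreated difference on the scale of log2(value + 10) was -0.97. The limma contrast called 0 genes raised and 1 lowered, Rxra (log2 -2.90, SE 0.35, adjusted p 0.015), and voom on the recovered reads also called 0 and 1. At an unadjusted p of 0.05 these fits gave 152 and 160, fewer than the 617 that chance gives. The residual holds the differences between lines in RA response, so few calls do not show that shRxr had little effect. Without the shCtbp2_RA library the fit had 1 residual degree of freedom, and the log2 difference of Rxra stayed at -2.90 (SE 0.24). With no filter limma called 0 genes (646 at an unadjusted p of 0.05, where chance gives 1194). Adjusted over the list alone, Plat (log2 -1.46) and Krt18 (-1.46) fell in the parietal endoderm list and Cldn6 (-1.23) and Krt18 in the epithelial list, and beside Rxra among the coregulators no other list gave a call.

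The response to RA in shRxr was then set against that in shGFP. Direct RA targets had a median difference of -1.77, below all matched lists, with 18 of 20 lower by at least 1. Stra8 (-3.42), Cyp26b1 (-3.32), Gas1 (-2.96), Mmp15 (-2.95), Hoxb6 (-2.90), Crabp2 (-2.69), Fndc1 and Gpr124 (each -2.53), Ptges (-2.52) and Foxa1 (-2.51) had the most negative differences. For Stra8 and Gpr124 most of the difference lay in the untreated libraries, with log2 differences from shGFP of 2.83 and 2.01 untreated and -0.59 and -0.52 in RA. RA still made Stra8 22.1-fold (19.4 to 25.4) and Cyp26a1 122-fold higher (51.8 to 376) in shRxr, and 18 of 20 targets were at least 2-fold higher. Anterior Hox (-1.54), parietal endoderm (-1.04) and primitive endoderm genes (-0.77) also had lower responses, all at percentile 0.01 or below. The pluripotency list had a median difference of 0.58, above all matched lists. The lists were matched on expression and not on size of response, and over all genes the shRxr slope on shGFP was 0.58. These percentiles therefore do not set the lists apart from a smaller response over all genes. The same holds for these lists' differences from shGFP in RA. Morc1 (2.59), Aire (2.39), Mfap3l (2.19), Rif1 (2.18), Slc23a1 (2.12), Ttpa and Tdgf1 (each 2.10) and Chic1 and Tet1 (each 2.0) were among the most positive differences. After the GC and length correction these genes had 1.01 (Chic1) to 2.60 (Aire), with Rif1 at 1.21, and the 10 most negative -3.38 to -2.34. Over all genes 690 responses were higher by at least 1 and 551 lower, and after the GC and length correction 180 were higher and 573 lower.

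The knock-downs were also compared with each other. The correlation across genes of the shCtbp2 and shRxr differences from shGFP was 0.08 untreated and 0.04 in RA, where unchanged lines set against the same shGFP libraries would give 0.50. The covariance was 0.0078 and 0.0144, against 0.128 simulated from the residual spread, which overstates the noise because it holds the differences between lines in RA response. In RA 41 genes were at least 2-fold higher in both lines and 144 lower in both, where independent lists would share 14.7 and 48.0. After the correction for GC content and length the correlation in RA was 0.38. Differences in RA response correlated at -0.05 (covariance -0.0187, simulated 0.256), or 0.30 after the correction. With only 1 control library per treatment, part of any overlap may come from the shared controls. Contrasts that share no library, 1 line untreated and the other in RA, gave 0.07 and 0.14. The shCtbp2 differences untreated and in RA correlated at 0.38, and those of shRxr at -0.10.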

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

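The test of the Dlk1-Dio3 cluster was chosen only after the result was seen, as were the correction for GC content and length and the median-of-ratios scaling; the bounds for these corrections were set before their outcome was known.

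A small set of genes went opposite ways with RA in different lines, which was not tested, since each group is 1 library. At least 2-fold higher in shGFP and lower in shCtbp2 were 7 genes, and 1 was lower in shGFP and higher in shCtbp2. The numbers were 2 for lower in shGFP and higher in shRxr, and 4 for lower in shCtbp2 and higher in shRxr. Fry had a log2 response of 1.23 in shGFP and -1.80 in shCtbp2, Gpr161 1.12 in shGFP and -1.41 in shCtbp2, and Mylpf -1.04 in shGFP and 1.48 in shCtbp2. After the correction for GC content and length the numbers were 3, 0, 0 and 2.

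The first pattern weighed is the number of genes lower in shCtbp2_RA than in shGFP_RA, 1831 against 288 untreated. The GC and length trend of this library accounts for part: after the correction 930 genes were at least 2-fold lower, above the bound of 384, and the median of the 1831 genes went from -1.24 (SD 0.33) to -0.81 (SD 0.51), with 632 of them still at least 2-fold lower. The 1831 genes have a median GC content of 46.2% against 50.1% of all tested and a median transcript length of 5.11 kb against 3.45 kb. The correction cannot tell a bias of this library from an RA response that follows GC content. Scaling to the library total also accounts for part but not for all of it alone, since 1270 genes were lower with median-of-ratios scaling (bound 421.5). With equal upper quartiles 965 were lower, against 298 untreated, and 886 were higher, so little excess of lower over higher genes was left. The correction and a rescaling were not applied together, so what would remain after both is not known. A lower level of the same genes already without RA is argued against by their corrected untreated median of -0.12, with 155 lower untreated, so an effect of Ctbp2 that appears with RA may remain for part of the genes, as may a difference between 2 cultures or library preparations that no replicate separates.

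The second pattern is the weaker RA response of the direct RA targets in both knock-down lines. The GC and length trend and the scaling both needed the median difference to come within 0.25 of 0 or inside the matched lists. After the correction it was -0.86 in shCtbp2 and -1.75 in shRxr, and with median-of-ratios scaling -0.78 and -1.77, all at percentile 0.01 or below. In shRxr the responses were smaller over all genes (slope 0.58 on shGFP), and the lists were not matched on size of response. The percentiles in shRxr therefore do not set the targets apart from that smaller response. In shCtbp2 the slope on shGFP was 1.19, and 0.99 after the correction. The same matched lists were used there, so its percentiles do not set the targets apart from other genes with strong responses. Against shGFP the list median was 0.30 untreated and -1.28 in RA in shRxr, so part of its smaller response lay in higher untreated levels, and 0.02 and -0.90 in shCtbp2. A role of Rxra or Ctbp2 in the full response may remain as a hypothesis that was not tested, as may a difference between the cultures in RA exposure or timing.

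The third pattern is the 226 genes that differed at least 2-fold in the same direction at both treatments in the shCtbp2 line. Its size depends on the pseudocount of 10, with 104 higher and 279 lower at a pseudocount of 1 and 26 and 28 at 50. After the GC and length correction 157 of them (69.5%) kept the difference under both treatments, which argues against the library trend as the cause. No chromosome had a median untreated difference of 0.3 or more in size, so the share of the genes on such chromosomes could only be 0%. The largest median in size was -0.12, on chromosome 14, which argues against gain or loss of a whole chromosome as the cause of the pattern. One part of it, the lower level of Meg3, Rian and Mirg, at least 2-fold at both treatments, may be silencing of the imprinted Dlk1-Dio3 cluster in the shCtbp2 culture, but this cannot be told apart from a wider fall. The 11 neighbours within 1 Mb had a median of -0.025 untreated (Begain had -1.08), within the bound of 0.3, and of -0.51 in RA (-0.56 after the correction), beyond it. Of these 11, 0 were at least 2-fold lower in RA, and 2 after the correction. Dlk1, which gives the cluster its name and was measured, was counted neither with the 3 transcripts nor among the neighbours. The 3 transcripts were also lower than shGFP in the shRxr line, by a log2 of 0.53 to 0.85, so a high level in the shGFP libraries may account for part. Set against shRxr, the log2 differences of shCtbp2 untreated and in RA were -1.57 and -2.29 for Meg3, -1.65 and -2.13 for Rian and -0.37 and -0.83 for Mirg. Such silencing may arise in culture without the hairpin, and 1 line cannot separate an effect of Ctbp2 from it.

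For the RA effect, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many genes: 1898 against 0 in the highest other split. Only 4 of the 10 splits, the real one included, part the 2 libraries of every line. In each false split the RA effect itself enters the residual, which works against calls there. With 10 splits, or with these 4, the share cannot fall under 0.05, so the comparison cannot tell the RA effect from chance.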

How the results depend on the processing

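The GC and length correction, median-of-ratios scaling, voom, and the fit without the shCtbp2_RA library were chosen only after the data were seen, as was the tolerance of 0.1 for calling correlations and slopes the same. The cause of a changed count was not tested unless the setting itself gives it (fewer genes or libraries). The untreated and RA libraries of a line were paired by the block on line in the main fit. The planned edgeR quasi-likelihood and DESeq2 tests were not run; of tests on the recovered reads only voom was. Equal totals changed nothing, because the deposited values already have them.

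The median responses of the direct RA targets kept their direction and size class under all alternatives, from 3.23 to 5.16 in shGFP, 2.23 to 4.16 in shCtbp2 and 1.74 to 3.0 in shRxr; their differences from shGFP lay between -0.92 and -0.67 for shCtbp2 and -1.91 and -1.38 for shRxr. Of other list medians 1558 were the same, 39 weaker, 52 stronger and 3 reversed. The 3 were neuroectoderm medians: the shRxr RA response was 0.14 with no filter, and with a mean of at least 100 the shRxr difference from shGFP in RA was 0.49 and in response 0.17. Of named gene values 1241 were the same, 19 weaker, 12 stronger and 0 reversed.

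With the GC and length correction, genes lower with RA numbered 531 in shGFP and 869 in shCtbp2; 930 were lower in shCtbp2 and 162 higher in shRxr than in shGFP in RA; response differences were 218 higher and 734 lower for shCtbp2 and 180 higher for shRxr. The slope of shCtbp2 on shGFP was 0.99, the correlation of shCtbp2 and shRxr 0.69 and their slope 0.61. limma called 2017 raised and 987 lowered by RA and 12 lowered in shCtbp2. Across settings r of shGFP and shCtbp2 was 0.74 to 0.80 (slope 0.99 to 1.26), of shGFP and shRxr 0.74 to 0.85 (slope 0.56 to 0.61) and of shCtbp2 and shRxr 0.43 to 0.69 (slope 0.45 to 0.61).

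With equal upper quartiles 886 genes were higher and 965 lower in shCtbp2 than in shGFP in RA, and 879 and 769 in the response difference; limma lowered 966 with RA and called 43 and 35 in shCtbp2. With median-of-ratios scaling 596 genes were higher in that comparison, 519 responses were higher, 1043 genes were lowered by RA, and 42 and 44 were called in shCtbp2.

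A mean of at least 100 left fewer genes: 933 higher with RA in shGFP, 1214 in shCtbp2, 302 higher and 108 lower in shRxr; untreated, 81 and 132 in shCtbp2 and 4 lower in shRxr; 148 lower in shRxr in RA; 208 responses higher in shCtbp2 and 281 lower in shRxr; at both treatments 32 and 75 in shCtbp2 and 3 higher in shRxr; limma calls 566 and 246 for RA and 1 and 3 for shCtbp2. With no filter 13 genes were lower untreated in shRxr, and limma called 0 and 0 in shCtbp2 and lowered 0 in shRxr. At an unadjusted p of 0.05 the 2 contrasts gave 1762 and 646, where chance gives 1194.

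With a pseudocount of 1, untreated counts were 532 lower in shCtbp2 and 135 and 48 in shRxr, at both treatments 279 lower and 25 opposite in shCtbp2 and 9 and 23, and 27 opposite, in shRxr, and limma called 1 and 3 in shCtbp2. With 50, RA counts were 1049 and 548 in shGFP, 1144 higher in shCtbp2, and 248 and 80 in shRxr; shCtbp2 differed at 68 and 45 genes untreated and 228 and 1065 in RA, shRxr at 9 and 3, and 233 and 143; responses differed at 146 and 896 in shCtbp2 and 380 and 221 in shRxr; at both treatments 26 and 28 in shCtbp2 and 1 higher in shRxr, with 2 and 0 opposite.

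limma without its trend lowered 8 genes in shCtbp2. Without the block on line it called 863 and 242 for RA, and leaving out each line in turn gave 375 to 1747 raised and 89 to 1498 lowered. voom called 1 and 3 in shCtbp2. Without the shCtbp2_RA library, with 1 residual degree of freedom, the RA counts were 565 and 207, shCtbp2 had 0 and 0, and shRxr 0 lowered (Rxra at the same log2 difference of -2.90, adjusted p 0.10).

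Genes near the floor of 3 reads are limited by depth.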

Other observations

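Some libraries stood apart in ways the groups do not name. Ribosomal protein genes took 4.10% of reads in shCtbp2_RA against 2.51% to 3.10% in the others, and 7370 genes had no read there against 6042 to 6344. Its deviation from the mean of all libraries had a Spearman correlation of -0.44 with transcript length, against 0.04 to 0.36 elsewhere. Mitochondrial genes took 1.20% to 1.58% of reads in the 6 libraries, and the 10 most abundant genes took 4.07% to 5.83%.

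Hsp90aa1, an abundant chaperone gene within 1 Mb of the Dlk1-Dio3 cluster and named here after its values were seen, stood at 12377 normalised reads in shGFP_UT and 5048 in shGFP_RA, 12164 and 4231 in shCtbp2, and 11057 and 12654 in shRxr. Lgals3 and Krt17, both higher in the shCtbp2 line, fell with RA over the lines (log2 -2.86 and -2.08), whereas Myl7 and Bhmt2, also higher there, rose with RA (1.37 and 1.08).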
